A study of Pseudomonas protegens with 6 samples.

How the data were processed

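RNA from 3 wild-type libraries and 3 hfq mutant libraries of *Pseudomonas protegens* H78 was analysed from one deposited gene table. Per the labels, cells were grown at 28 °C in KMB medium to an OD600 of 5.0 to 6.0, RNA was purified on Qiagen RNeasy kits with a DNase set, and ribosomal RNA was removed before fragmentation and cDNA synthesis. The submitters' processing notes name Trimmomatic, TopHat2 2.0.9 and HTSeq 0.6.1, without saying what each was used for. The genome build, the annotation and the use of strand in counting are not given in the sources used here, so positions are those of the deposited table.

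The authors deposited an expected count per gene and library, which was not normalized, and an FPKM value, scaled by gene length and library size. Per the file headers, the authors' own comparison gives a mean signal per group, which is a scaled count, a fold change as a ratio, its log2 value, a p-value and an adjusted p-value, and the tool behind it is not given in the sources used here. These columns and the FPKM values entered no test. Expected counts, given to at most 2 decimals, were whole (a fraction of exactly 0, no tolerance) in 99.6% to 99.7% of genes per library. In 26 genes they were split between features, among them ribosomal RNA copies, rebB_1_2, rebB_2, tuf_1 and the RNase P RNA H78_05285, and the values of such genes are uncertain.

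Expected counts were rounded to whole numbers. Genes were kept with filterByExpr (minimum count 10), which left 5816 of 6446, and libraries were scaled with TMM factors. The groups were compared with the two-sided quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are mutant over wild type, the SE is the absolute log2 fold change over the square root of F, and levels in CPM were scaled to the TMM-adjusted library size. Where every mutant library held 0 counts, a bound was set from 3 counts over the group. Total counts were 4674613 to 6253710 per library, of which 2090339 to 3891051 were on coding sequences. Tested on simulated data with 200 changed genes, the fit recovered 91 of 98 genes changed 2-fold and 99 of 99 changed 4-fold, and called 8 of 5570 unchanged genes, over 5767 genes run. The simulated changes were few and balanced up and down. These rates therefore do not cover the real data, where 63.5% of tested genes changed.

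Before the data were examined, 39 gene lists were fixed by symbol and product patterns, with the tests, the rule for named genes and most alternatives. A gene could enter more than 1 list. Copy suffixes were ignored and joint names split in matching, and product patterns were used only for genes with no symbol. Some patterns took in genes at odds with the list's name: fusA of fusaric acid resistance among translation factors, choline transport genes among prophage genes, isopropylmalate synthases in the tricarboxylic acid cycle, peptidylarginine deiminases in the arginine deiminase list a TatD deoxyribonuclease in RNA decay, the lipoate enzyme genes lipA and lipB among exoenzymes, the mtl polyol genes in the glucose and gluconate list, and HflC or HflK family genes from elsewhere on the chromosome in the hfq locus list. Other such genes may remain, since members were not all checked by hand. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and the 37 p-values were adjusted together.

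The rule named hfq, then the 8 genes with the highest and the 8 with the lowest log2 fold change among genes past the threshold with a mean of at least 50 counts, groups that did not overlap, and a symbol or an informative product. It then named up to 4 members per described list with the largest change among those past the threshold with that mean. Any member of the antibiotic, siderophore, Gac/Rsm, sigma factor and hfq locus lists could be named, and the 3 most abundant genes for shares of counts. Genes outside the rule are said to be chosen after their values were seen, except acsA_1, which only marks a position.

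Replicates of a group differed beyond sampling noise (chi-square per gene of 5.07 to 12.5) and were each counted as 1 replicate. Alternatives were RLE, total-count and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter or a mean of at least 50 counts, a robust prior, glmTreat against a 1.5-fold change, the replicate number as a block, removal of ribosomal and transfer RNA and the 10 most abundant genes, each library left out in turn, camera with an estimated correlation, fry, and symbol matches only. After the data were seen, coding sequences alone, strict symbol matching, lists without the members named above as at odds with their name, and lists without hfq were added. Figures were drawn with matplotlib 3.10.9.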

Results

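RNA was sequenced from *Pseudomonas protegens* H78, a bacterium of a species known for making several antibiotics, and from its hfq mutant. Hfq is an RNA chaperone that binds small RNAs and messenger RNAs and acts with the Crc protein in the carbon catabolite repression of pseudomonads. Both strains were grown at 28 °C in KMB medium to the late exponential phase (OD600 of 5.0 to 6.0), with 3 libraries per strain. The gene table listed 6446 features, of which 6290 were coding sequences. Total counts were 4674613, 5256600 and 4946338 in wild-type replicates 1, 2 and 3 and 4987942, 6253710 and 4876809 in mutant replicates 1, 2 and 3. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

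A few non-coding RNAs took a large part of the counts. The transfer-messenger RNA ssrA, which rescues stalled ribosomes, held 34.7% ± 0.799 of the wild-type counts and 28.8% ± 0.884 of the mutant counts (SD, n = 3 each). The RNase P RNA H78_05285, which processes transfer RNA precursors, held 14.7% ± 1.25 and 8.80% ± 0.183. CrcZ, a small RNA known to relieve catabolite repression by binding Hfq, held 4.13% ± 0.165 and 7.42e-04% ± 7.62e-05. Coding sequences held 45.2% ± 0.542 and 61.1% ± 1.02.

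The single comparison asks how the transcriptome of the hfq mutant differs from that of the wild type. CrcZ and the related crcY were nearly lost in the mutant. Genes that fell included 17 of 17 for pyoluteorin, 3 of 3 for hydrogen cyanide, 11 of 11 for pyochelin and 18 of 20 for type VI secretion. Genes that rose included 41 of 47 of the respiratory chain and 41 of 46 for the flagellum. In an amino acid transport list that also covers polyamine and peptide transporters, 64 of 96 rose. Each of these lists passed camera with a preset correlation and none with an estimated correlation. The largest rises were in genes with few counts in the wild type, such as the fusaric acid resistance gene fusA, which went from 3.86 ± 0.820 to 847 ± 52.6 CPM (SD, n = 3 each).

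The mutated gene hfq (H78_00584, positions 662937 to 663197, plus strand) had 435, 547 and 538 counts in wild-type replicates 1, 2 and 3 and 0 counts in each mutant library. Its wild-type level was 95.8 ± 6.41 CPM (SD, n = 3), and its level was at least 486-fold lower in the mutant, against a floor of 0.197 CPM set by 3 counts over the mutant group. This floor covers counting error only. Downstream of hfq, the genes hflX, hflK and hflC_1 fell, with log2 fold changes of -0.45 (SE 0.08), -0.88 (SE 0.07) and -1.18 (SE 0.08). Upstream of it, miaA and mutL rose, by 0.36 (SE 0.08) and 0.48 (SE 0.08). Of 9 tested members of the hfq locus list, 2 rose, 4 fell and 3 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0289, and adjusted p = 0.253 with an estimated correlation). The 3 that did not pass, hflC_2, H78_06406 and H78_06408, are HflC or HflK family genes that lie elsewhere on the chromosome. The list did not pass without mutant replicate 2 (adjusted p = 0.0513). It also did not pass with strict symbol matching (adjusted p = 0.0556) or without hfq itself (adjusted p = 0.382), 2 alternatives chosen after seeing the data.

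CrcZ (H78_05479, positions 6019799 to 6020193) fell from 38768 ± 1136 to 7.90 ± 0.796 CPM (SD, n = 3 each), a 4907-fold difference (log2 fold change -12.26, SE 0.15, adjusted p = 1.22e-13, edgeR), and was lower in 3 of 3 mutant libraries. Its relative crcY (H78_04226, positions 4660883 to 4661288) fell from 1302 ± 53.4 to 4.54 ± 1.08 CPM (SD, n = 3 each), a 287-fold difference (adjusted p = 1.29e-12, edgeR), also in 3 of 3 mutant libraries. The sensor kinase gene cbrA rose by 0.41 (SE 0.09). The gene crc, singled out after its values were seen, had a log2 fold change of 0.11 (SE 0.09) and did not pass, and its sign was negative under total-count and upper-quartile scaling and with a filter at a mean of 50 counts. In the Crc and CbrAB list, 1 of 5 members rose, 2 fell and 2 did not pass, as also adjusted over the list alone (camera adjusted p = 1.39e-08, and adjusted p = 0.126 with an estimated correlation). With coding sequences alone, which leaves out CrcZ and crcY, its adjusted p was 0.866 and its median went from -0.079 to 0.10.

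**Figure D1:**
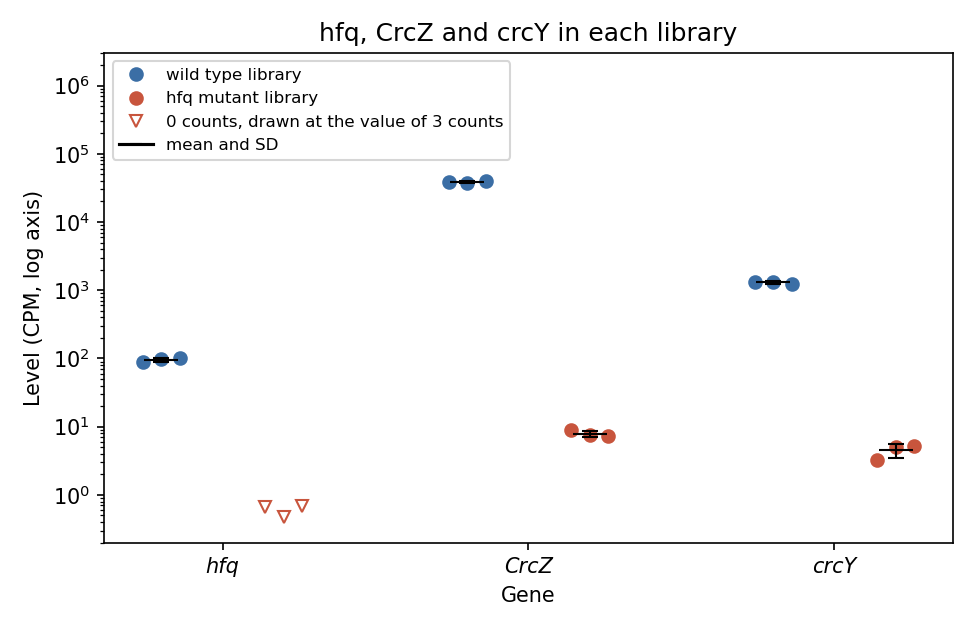
Level of hfq, CrcZ and crcY in CPM (log axis) in each of the 3 wild-type (blue) and 3 hfq mutant (red) libraries, with group mean and SD in black; open triangles are libraries with 0 hfq counts, drawn at the value of 3 counts in that library. The mean of CrcZ was 38768 CPM in the wild type and 7.90 CPM in the mutant.

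Of 5816 genes tested, 3691 changed at an adjusted p below 0.05 (edgeR), or 63.5%, with 1827 up and 1864 down. Changes of at least 2-fold numbered 1386, with 656 up and 730 down. The groups did not overlap in 3977 of the genes tested, or 68.4%, where chance gives 10%. Total-count scaling moved the median of all tested genes by -0.18 on the log2 scale and upper-quartile scaling by -0.14, with 1414 genes up and 2354 down under the former. In the authors' deposited comparison, 3063 genes had an adjusted p below 0.05, of which 3041 were called here in the same direction.

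The highest log2 fold change among the named genes belonged to H78_04834, annotated as a subunit of a type IIA topoisomerase and lying beside acsA_1 (11.43, SE 0.19). This feature is only 264 nt long, and its product name was not checked. Its counts were 1, 5 and 3 in the wild type and 6950, 10674 and 7433 in the mutant. The iron-dependent alcohol dehydrogenase gene H78_05826 followed, from 15.8 ± 1.90 to 6722 ± 1223 CPM (SD, n = 3 each). The adjacent genes yiiM, for detoxification of base analogs, and pqqI, for an aminotransferase, rose by 8.49 (SE 0.15) and 7.84 (SE 0.15). The fusaric acid resistance genes fusE, fusA and fusBCD rose by 8.12 (SE 0.12), 7.77 (SE 0.14) and 7.19 (SE 0.12). The 2-phenylethanol efflux gene pedA rose by 7.64 (SE 0.19). At the other end, after CrcZ, hfq and crcY, the RebB protein genes rebB_1_2 and rebB_2 fell, with log2 fold changes of -7.09 (SE 0.33) and -6.83 (SE 0.33), and their values are uncertain because reads were split between them or other copies.

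**Figure D2:**
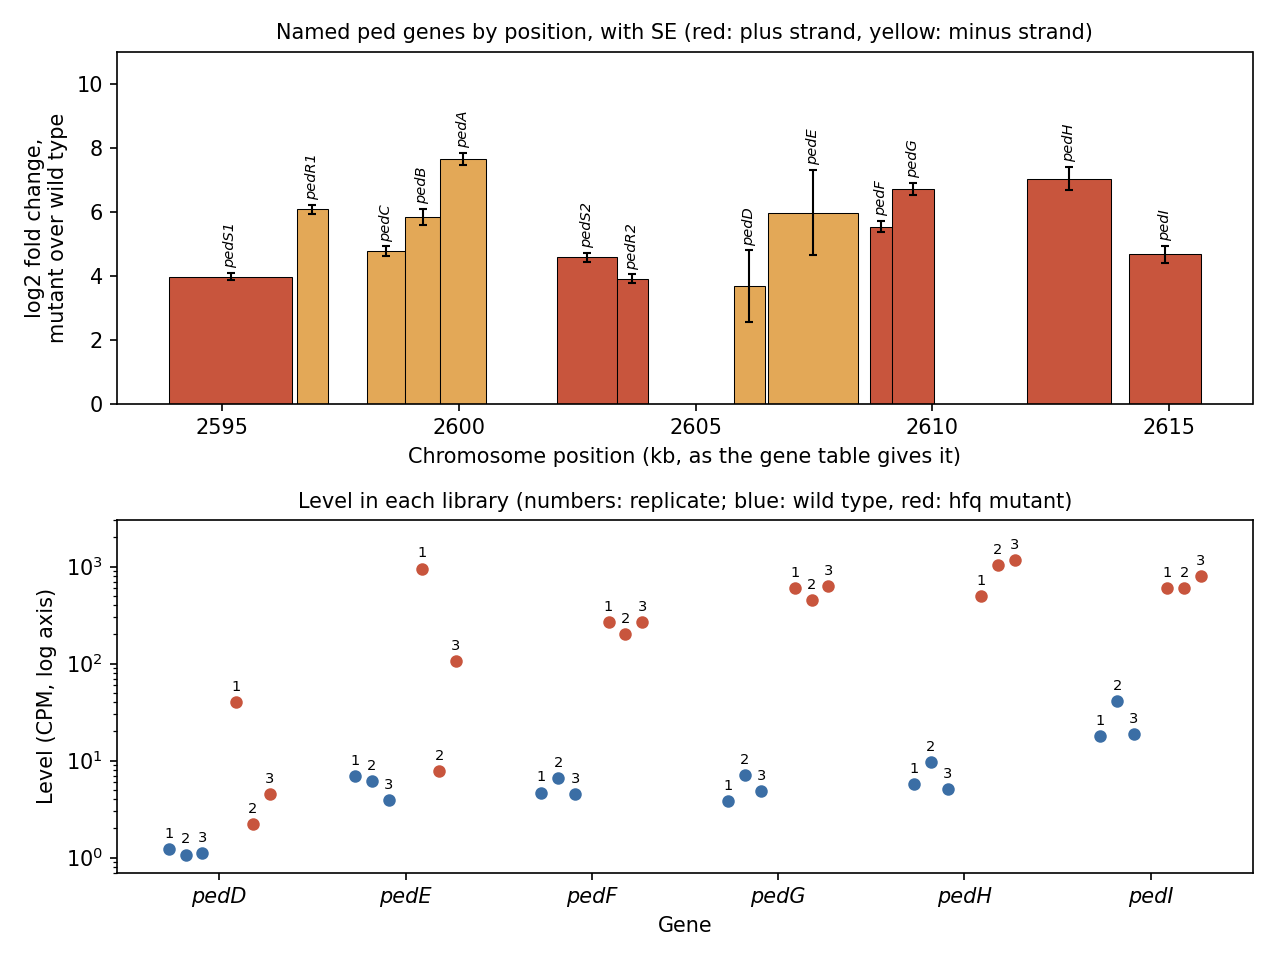
Top: log2 fold change (hfq mutant over wild type, 3 libraries each, bars with SE) of 13 ped genes by chromosome position in kilobases, chosen after their values were seen. Bottom: level in CPM (log axis) of 6 of them in each library, with replicate numbers; pedE ranged from 7.80 to 954 CPM among the mutant libraries and pedG from 457 to 630.2 CPM.

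Antibiotic genes fell in several groups. All 17 tested genes for pyoluteorin, a chlorinated antibiotic, fell, also adjusted over the list alone, with a median log2 fold change of -3.58 (camera adjusted p = 3.59e-20, and adjusted p = 0.231 with an estimated correlation). The halogenase gene pltA went from 1334 ± 829 to 15.4 ± 0.326 CPM (SD, n = 3 each), and pltL, pltE and pltD changed by -6.56 (SE 0.45), -5.58 (SE 0.43) and -5.38 (SE 0.36). The pltA counts in wild-type replicates 1, 2 and 3 were 3510, 12710 and 5403, and its log2 fold change of -6.43 (SE 0.41) was -5.81 without wild-type replicate 2. The 3 hydrogen cyanide synthase genes hcnA, hcnB and hcnC fell, also adjusted over the list alone, with log2 fold changes of -1.75 (SE 0.14), -1.87 (SE 0.08) and -1.94 (SE 0.09) (camera adjusted p = 3.63e-04, and adjusted p = 0.231 with an estimated correlation). Of 7 tested genes for the antibiotic 2,4-diacetylphloroglucinol, 5 fell and 2 did not pass, as also adjusted over the list alone (camera adjusted p = 0.0199, and adjusted p = 0.231 with an estimated correlation). The hydrolase gene phlG changed by -3.05 (SE 0.13) and the repressor gene phlF by -1.86 (SE 0.18). The biosynthesis genes phlA and phlC changed less, by -1.15 (SE 0.15) and -0.80 (SE 0.18), and phlB was not tested. The permease gene phlE had 0.20 (SE 0.20) and did not pass. The largest falls were thus not in biosynthesis genes. The polyketide synthase gene phlD had -0.45 (SE 0.20) and did not pass, but passed without wild-type replicate 1 (adjusted p = 0.0493) and under total-count (adjusted p = 0.0243) and upper-quartile scaling (adjusted p = 0.0222). The regulator gene phlH had -0.38 (SE 0.11), which did not pass without wild-type replicate 2 (adjusted p = 0.0529) or in DESeq2 (adjusted p = 0.0620).

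All 4 genes for the antibiotic pyrrolnitrin fell, also adjusted over the list alone, with prnD at -2.07 (SE 0.22) and prnC at -1.75 (SE 0.14). The list did not pass (camera adjusted p = 0.0573), but passed without wild-type replicate 1 (adjusted p = 0.0252) or 3 (adjusted p = 0.0399) and with the replicate number as a block (adjusted p = 0.0449). The 3 synthetase genes of the lipopeptide orfamide fell, also adjusted over the list alone, with ofaC at -1.08 (SE 0.11), and the list did not pass (camera adjusted p = 0.117). In the Fit insect toxin list, 2 of 8 members rose and 4 fell (3 and 5 adjusted over the list alone). The regulator genes fitG and fitH rose by 1.55 (SE 0.12) and 1.16 (SE 0.13), and the cytotoxin gene fitD changed by -0.86 (SE 0.14). This list had a median of -0.82 and did not pass (camera adjusted p = 0.998), and fry, with an adjusted p of 0.336, pointed up. No feature matched the rhizoxin or toxoflavin lists.

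Genes for iron uptake fell unevenly. All 11 genes of the list for the siderophore pyochelin fell, also adjusted over the list alone, with a median of -3.95 (camera adjusted p = 3.63e-04, and adjusted p = 0.511 with an estimated correlation). The synthetase gene pchF went from 251 ± 159.8 to 10.5 ± 2.03 CPM (SD, n = 3 each), with 410, 1500 and 2144 counts in wild-type replicates 1, 2 and 3, and pchE and pchD changed by -4.67 (SE 0.49) and -4.67 (SE 0.62). Of 21 tested genes for the siderophore pyoverdine, 11 fell, 3 rose and 7 did not pass, as also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.382). The sigma factor gene pvdS, which controls pyoverdine synthesis, changed by -1.76 (SE 0.26) and the transporter gene pvdE by -1.07 (SE 0.16). The regulator gene fpvR rose by 0.88 (SE 0.10). The pvdO copies differed: pvdO_2, apart from the other pvd genes, rose by 1.27 (SE 0.09), and pvdO_1 changed by -0.50 (SE 0.19). The copy next to pvdF, pvdO_3, had 0.089 (SE 0.30) and did not pass. Of 72 genes in the list for other iron uptake and storage, 34 fell and 9 rose, as also adjusted over the list alone (camera adjusted p = 0.0371, and adjusted p = 0.443 with an estimated correlation). The falls include 3 ferripyoverdine receptor genes that are also in the pyoverdine list. The outer membrane receptor gene H78_00897 changed by -4.45 (SE 0.27), the heme oxygenase gene hemO by -2.66 (SE 0.31), and the iron transporter gene H78_03472 by -2.76 (SE 0.33), or by -3.45 without mutant replicate 2. This list did not pass under total-count scaling (adjusted p = 0.0642), without wild-type replicate 2 (adjusted p = 0.0523) or 3 (adjusted p = 0.0505), or with symbol matches only (adjusted p = 0.102).

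Regulator genes moved both ways. In the Gac/Rsm pathway, which controls secondary metabolism, the sensor kinase gene ladS rose by 1.97 (SE 0.08) and rsmA, for an RNA-binding regulator, by 1.12 (SE 0.13), and the sensor gene retS changed by -0.56 (SE 0.08). The response regulator gene gacA had -0.082 (SE 0.08) and did not pass, but passed under total-count scaling (-0.26), under upper-quartile scaling (-0.22) and with a filter at a mean of 50 counts (-0.22). Of 6 tested members 2 rose and 1 fell, as also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.382). Of 50 sigma and anti-sigma factor genes, 29 fell and 12 rose, as also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.217). The gene of the stationary-phase sigma factor, rpoS, changed by -0.71 (SE 0.08), and that of the housekeeping sigma factor, rpoD, by 0.81 (SE 0.09).

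Respiratory genes rose together. Of 47 tested members, 41 rose and 2 fell, as also adjusted over the list alone, with a median of 2.05, a 4.15-fold difference (camera adjusted p = 1.30e-24, and adjusted p = 0.108 with an estimated correlation). The cytochrome c oxidase gene coxA went from 175 ± 12.6 to 2712 ± 259.7 CPM (SD, n = 3 each), and ctaG, ctaC and the cytochrome o oxidase gene cyoA_2 rose by 3.71 (SE 0.11), 3.62 (SE 0.09) and 3.30 (SE 0.13). All 13 nuo genes of NADH dehydrogenase, singled out after their values were seen, rose by 1.93 (nuoM) to 2.34 (nuoN). Of 9 ATP synthase genes 8 rose, as also adjusted over the list alone, with a median of 1.09 and atpB at 1.25 (SE 0.08) (camera adjusted p = 0.00200, and adjusted p = 0.445 with an estimated correlation). In the tricarboxylic acid cycle list, 14 of 23 rose and 5 fell, as also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.289). The succinate dehydrogenase gene sdhB rose by 1.33 (SE 0.08), and the isocitrate dehydrogenase genes icd_1 and icd_2 changed by -1.23 (SE 0.08) and 1.05 (SE 0.09). Of 13 anaerobic respiration and arginine deiminase genes, 8 fell and 3 rose, as also adjusted over the list alone, with the nitrite reductase gene nirK at -1.03 (SE 0.09), and the list did not pass (camera adjusted p = 0.282).

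Most genes in the amino acid transport list rose as well. Its pattern also took in names of polyamine, peptide, glycine betaine and taurine transporters, among them potF. Of 96 tested members, 64 rose and 11 fell, as also adjusted over the list alone. The median was 0.92 (camera adjusted p = 1.01e-10, and adjusted p = 0.101 with an estimated correlation). The substrate-binding protein gene potF went from 21.2 ± 5.87 to 1419.8 ± 50.9 CPM (SD, n = 3 each), and the general amino acid transporter genes aapQ and aapJ rose by 4.17 (SE 0.11) and 3.71 (SE 0.11). In the glucose and gluconate uptake list, whose pattern also took in mannitol genes, 17 of 33 rose and 9 fell, as also adjusted over the list alone, with a median of 0.60 (camera adjusted p = 4.86e-06, and adjusted p = 0.108 with an estimated correlation). Its members named by the rule were the transporter genes mtlF, mtlG and mtlE (4.55 (SE 0.14), 4.55 (SE 0.16) and 4.33 (SE 0.15)) and the dehydrogenase gene mtlD (4.27 (SE 0.15)), which act on polyols such as mannitol and not on glucose. Without the 8 mtl genes, an alternative chosen after seeing the data, 10 of the others rose and 8 fell, the median was -0.13 and the list did not pass (adjusted p = 0.163).

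Catabolic lists were divided, and none of the 4 described here passed. Of 9 histidine catabolism genes, 7 fell and 2 rose, as also adjusted over the list alone, with the urocanate hydratase gene hutU at -4.20 (SE 0.16) and hutF at 1.39 (SE 0.11) (camera adjusted p = 0.135). In branched-chain amino acid catabolism, 7 of 17 rose and 3 fell, as also adjusted over the list alone, with mmsA_2 and mmsB of valine breakdown at 3.89 (SE 0.11) and 3.004 (SE 0.11). That list had a median of -0.017 but a mean of 0.64 and a test that pointed up (camera adjusted p = 0.0758), and it passed without mutant replicate 1 (adjusted p = 0.0252) and with symbol matches only (adjusted p = 0.0489). Of 42 aromatic compound catabolism genes, 11 rose and 11 fell, as also adjusted over the list alone, with the transporter gene pcaK at 4.06 (SE 0.15) and the thiolase gene pcaF at 3.33 (SE 0.20) (camera adjusted p = 0.292). Of 48 fatty acid degradation genes, 19 fell and 9 rose, as also adjusted over the list alone, with the dehydrogenase genes H78_05953 and H78_02345 at -4.51 (SE 0.18) and 4.45 (SE 0.15) (camera adjusted p = 0.448). The first of these lies between cdhC_2 and cdhB, and whether it serves fatty acid degradation was not checked.

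Flagellar genes rose and type VI secretion genes fell. Of 46 flagellar genes, 41 rose and 1 fell (42 and 1 adjusted over the list alone), with a median of 0.97 (camera adjusted p = 1.50e-09, and adjusted p = 0.246 with an estimated correlation). The ring protein genes flgI and flgH and the hook-associated protein gene flgK rose by 1.53 (SE 0.09), 1.48 (SE 0.08) and 1.42 (SE 0.08). Of 20 genes of type VI secretion, which injects effectors into other cells, 18 fell and 2 did not pass, as also adjusted over the list alone, with a median of -1.95 (camera adjusted p = 1.92e-12, and adjusted p = 0.108 with an estimated correlation). The gene hcp, for the tube protein, went from 180.4 ± 23.5 to 16.6 ± 2.16 CPM (SD, n = 3 each), and the ATPase gene clpV and the spike gene vgrG changed by -2.79 (SE 0.12) and -2.31 (SE 0.10). Chemotaxis genes numbered 25 up and 11 down of 53, as also adjusted over the list alone, with cheY at 1.43 (SE 0.08) and the receptor gene H78_02601 at -2.36 (SE 0.13) (camera adjusted p = 0.135). Type IV pilus genes numbered 7 up and 8 down of 30 (7 and 7 adjusted over the list alone), with pilJ at -0.82 (SE 0.13) (camera adjusted p = 0.660). Exopolysaccharide and biofilm genes numbered 16 up and 18 down of 48 (16 and 19 adjusted over the list alone), with pgaC at 1.47 (SE 0.08) and the alginate lyase gene H78_03638 at -4.54 (SE 0.44) (camera adjusted p = 0.660). Exoenzyme genes numbered 10 up and 12 down of 29, as also adjusted over the list alone, with the secreted protease gene aprA at -2.63 (SE 0.15) (camera adjusted p = 0.382). Its pattern also took in lipA and lipB, which here are lipoate enzyme genes and not lipases.

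**Figure D3:**
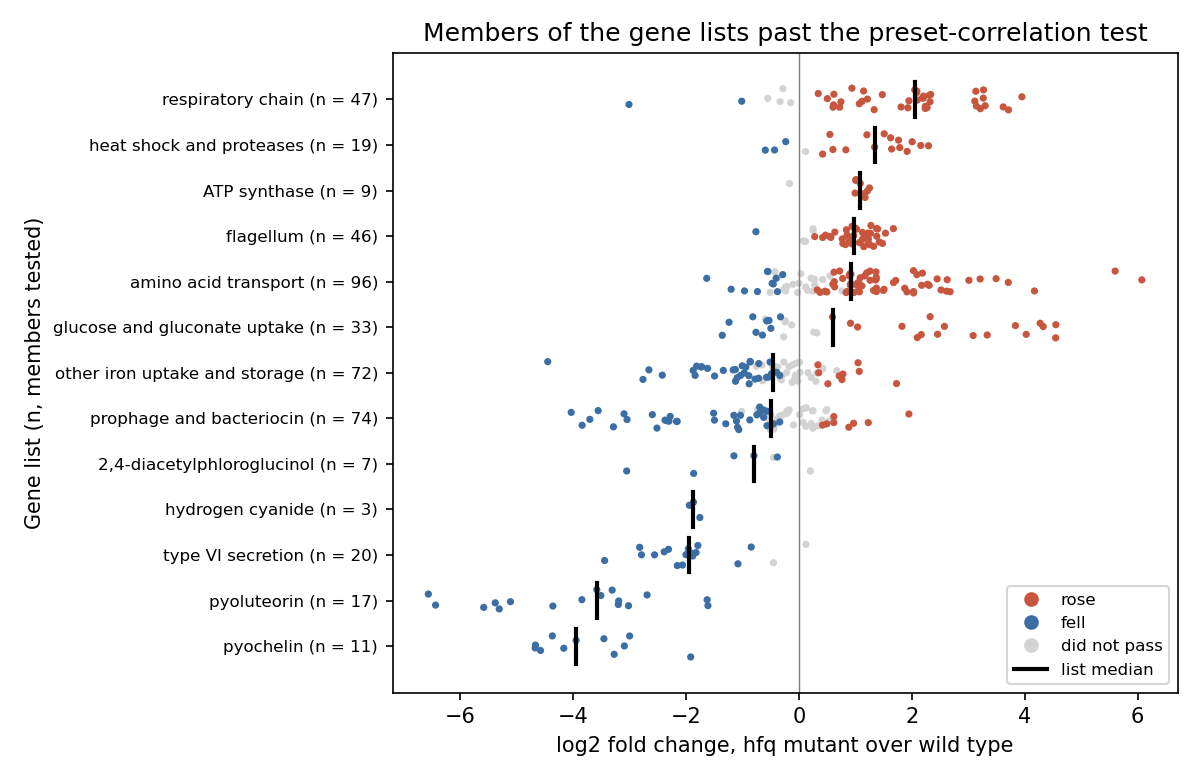
Log2 fold change (hfq mutant over wild type, 3 libraries each) of each tested member of 13 gene lists that passed camera with the preset correlation, with the list median as a black bar; red points rose, blue points fell and gray points did not pass. Medians run from -3.95 for pyochelin to 2.05 for the respiratory chain, and none of these lists passed with an estimated correlation.

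Heat shock genes rose, and other stress genes moved both ways. Of 19 heat shock and protease genes, 15 rose and 3 fell, as also adjusted over the list alone, with a median of 1.34 (camera adjusted p = 4.25e-06, and adjusted p = 0.443 with an estimated correlation). The small heat shock protein gene ibpA, the protease subunit gene hslU and the co-chaperonin gene groS rose by 2.29 (SE 0.11), 2.16 (SE 0.09) and 1.92 (SE 0.13). Of 29 oxidative stress genes, 14 fell and 8 rose, as also adjusted over the list alone, with the catalase gene katE at -2.49 (SE 0.11) and H78_04442, for a protein with a thioredoxin domain, at 2.29 (SE 0.11), and the list did not pass (camera adjusted p = 0.421). Of 29 osmotic stress and storage genes, 13 fell and 6 rose, as also adjusted over the list alone, with ectB of ectoine synthesis at -1.995 (SE 0.14), and the list did not pass (camera adjusted p = 0.135). Of 74 prophage and bacteriocin genes, 34 fell and 8 rose (33 and 8 adjusted over the list alone), with a median of -0.49 (camera adjusted p = 0.00399, and adjusted p = 0.511 with an estimated correlation). The phage prohead gene H78_03735 and the terminase gene H78_03739 changed by -3.56 (SE 0.21) and -3.04 (SE 0.18), and H78_02935, a choline transporter gene that the pattern took in, by -3.84 (SE 0.16).

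The lists for ribosomal proteins, translation, RNA decay and efflux did not pass. Of 55 ribosomal protein genes, 29 rose and 3 fell, as also adjusted over the list alone, with rpsI at 1.20 (SE 0.10) and rpsO at -2.08 (SE 0.09) (camera adjusted p = 0.186). Of 46 translation factor and tRNA synthetase genes, 19 rose and 8 fell, as also adjusted over the list alone, with trpS at -1.15 (SE 0.08) (camera adjusted p = 0.569). This list held fusA, which here is a fusaric acid resistance gene and not an elongation factor. In RNA processing and decay, 10 of 27 rose and 10 fell, as also adjusted over the list alone, with the ribonuclease E gene rne at 1.002 (SE 0.08). Its median was 0.052, while its mean, which depends on the fitted value of hfq, and its test pointed down (camera adjusted p = 0.636). Of 43 efflux genes, 15 fell and 11 rose, as also adjusted over the list alone, with mexE, mexF and oprN at -2.72 (SE 0.13), -2.41 (SE 0.10) and -2.61 (SE 0.10) (camera adjusted p = 0.441, or 0.00494 with symbol matches only). Across the 37 lists tested, 15 passed camera with the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.101. With fry, which asks whether a list's genes move one way and does not compare them with other genes, 31 passed.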

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

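Alternatives with coding sequences alone, strict symbol matching, lists without members at odds with their name and lists without hfq were chosen after seeing the data. Under the other scalings, tests and filters apart from glmTreat, 2839 to 3797 genes changed. The lowest count came with the filter at a mean of 50 (3959 genes tested) and the highest with upper-quartile scaling (5816 tested). DESeq2 called 2998 of 6180 genes tested, the smallest share among these settings. Leaving out each library gave 3386 to 3509 genes, with 1374 to 1470 changed at least 2-fold, and 14 to 16 lists past the threshold. By its construction glmTreat, which asks for more than a 1.5-fold change, called fewer genes, 1674, of which 862 rose and 812 fell. The 15 lists past the threshold became 0 with an estimated correlation and 31 with fry, and the cause was not tested. The replicate numbers did not pair the libraries (correlations of deviations of 0.0248, 0.0275 and 0.0237), and with the replicate block 3669 genes and 16 lists passed. A turn of a list below is one of the direction of its test. With coding sequences alone, which leave out CrcZ and crcY, the Crc and CbrAB list turned with its median (from -0.079 to 0.10). Other turns were in lists that did not pass, and their cause was not tested. The Fit list turned, while its median stayed negative, under fry (median -0.82), total-count scaling (-0.99), the replicate block (-0.84) and without wild-type replicate 1 (-0.72) or 2 (-0.69), with medians of -0.91 to -0.64 over the 6 libraries left out. With symbol matches only, exoenzymes turned with their median (from -0.19 to 0.69) and RNA processing with a median that stayed positive (0.39). RNA processing turned without hfq and translation factors without fusA, with medians that stayed positive (0.060 and 0.028). The glucose and gluconate list did not pass without its mtl genes, which are at odds with its name (median from 0.60 to -0.13, adjusted p = 0.163). The gene crc turned to -0.067 under total-count scaling, -0.029 under upper-quartile scaling and -0.023 with the filter at a mean of 50. Of the other comparisons with an alternative, 3160 for named genes kept direction and side of the threshold, 6 lost a call and 7 gained one, and for lists 536 kept the direction of the test and the side of the threshold, 23 lost a call and 22 gained one. In 16 of these 536 the median changed sign, 5 of them under total-count scaling, which moved the median of all genes by -0.18: Gac/Rsm (-0.078), chemotaxis (-0.049), aromatic catabolism (-0.11), RNA processing (-0.12) and translation factors (-0.15). The others were type IV pili, branched-chain catabolism, exopolysaccharides and fatty acid degradation, with RLE, a library left out or symbol matches only. Alternatives planned for normalized values were not run because counts were given. Without the count filter 487 genes below it were tested in edgeR, and 72 of them passed. Of those tested, rsmY (adjusted p = 0.318) and rsmZ (adjusted p = 0.116) did not pass, with 5 and 28 counts over the 6 libraries, and rsmX, with 0, could not be tested.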

Other observations

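The tests reported here, apart from the splits of the libraries, were chosen only after the results were seen, as were the genes and chromosome runs named.

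Some changed genes also lay side by side on the chromosome. How many such runs genes in random order would give was not tested. Runs of at least 5 neighbouring genes that passed the test in one direction with a log2 fold change of at least 1.5 in size numbered 31, with 17 up and 14 down. The ped genes, which in other pseudomonads serve alcohol oxidation, lay in a run of 8 genes (positions 2592737 to 2601794, median 5.32) and one of 15 genes (2602075 to 2620106, median 4.58). The 13 ped genes rose by 3.68 (pedD, or 1.48 without mutant replicate 1 and 4.28 without replicate 2) to 7.64 (pedA), with the regulator gene pedR1 at 6.07 (SE 0.13) and pedH at 7.03 (SE 0.35). The pedD rise did not pass in limma-voom (adjusted p = 0.120) or with a robust prior (adjusted p = 0.151). A run of 5 genes from pqqB_2 to pqqM, for the cofactor pyrroloquinoline quinone, rose with a median of 2.09, and the branched-chain amino acid transporter run from livJ to livF with 2.28. Among runs that fell, 6 genes around the RebB genes had a median of -4.83, 5 genes with 3 fatty acid desaturases -3.63, and 6 genes with cdhC_2 and cdhB -3.70. Members of the tested lists formed runs as well. The 17 pyoluteorin genes and the 13 nuo genes each made a single run, and the 11 pyochelin genes lay in a run of 16. Type VI secretion genes lay in runs of 9 and 10 genes. Counts of members in such lists are therefore not counts of independent genes.

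Other non-coding RNAs differed too. The RNA H78_05624, annotated P24, had 387, 362 and 387 counts in the wild type and 15, 32 and 9 in the mutant, a log2 fold change of -4.29 (SE 0.19). The RNA phrS changed by -0.55 (SE 0.10), and the cspA element H78_02293, whose span overlaps capA, by 1.25 (SE 0.11). The transfer-messenger RNA ssrA had -0.086 (SE 0.12) and did not pass, but passed at -0.27 under total-count scaling.

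The regulatory RNAs of the Gac/Rsm pathway were nearly absent from the counts of both strains, with 0 counts for rsmX, 5 for rsmY and 28 for rsmZ over the 6 libraries. Reads on repeated features were not all left uncounted, since 26 features held split counts and ribosomal RNA copies held at least 12917 counts per library. Overlaps and repeats at rsmX, rsmY and rsmZ themselves were not examined, so a loss of reads there stays open. A loss of RNAs shorter than 200 nt before sequencing is a candidate explanation, since 4 of 47 annotated non-coding RNAs below that length reached a mean of 10 counts, against 17 of 18 longer ones (Fisher's exact test, two-sided, p = 5.31e-11). The 47 include rsmX, rsmY and rsmZ themselves. The 75 transfer RNAs held 1 count and the 6 5S ribosomal RNAs 0 over the 6 libraries. Ribosomal RNA was removed before cDNA synthesis, so the 5S counts cannot tell a loss by length from that removal. No biological explanation was tested.

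The dehydrogenase gene pedE had 4340, 49 and 467 counts in mutant replicates 1, 2 and 3, and its log2 fold change of 5.97 (SE 1.33) was 3.29 without mutant replicate 1 and 6.56 without replicate 2, and did not pass in limma-voom (adjusted p = 0.172) or with a robust prior (adjusted p = 0.0752). Scaling or depth of one library is argued against by pedG, nearby, whose highest mutant CPM was 1.38 times its lowest, and wild-type RNA in a mutant library by 0 hfq counts over the 3 mutant libraries. Reads shared with the paralog pedH are argued against as the cause: pedH had 2258, 6574 and 5102 counts in the same libraries, fewest where pedE had most, and the ratio of pedE to pedH, which sequence would fix, varied 258-fold, and 0 of their 12 values held a fraction. The highest mutant sum of pedE and pedH CPM was 1.38 times the lowest, and the adjacent pedD, which is no dehydrogenase, varied with pedE by a factor of 17.96. In *Pseudomonas putida* lanthanides are known to switch expression between pedE and pedH, but the labels record nothing on them and no biological explanation was tested.

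The rise of the respiratory chain and amino acid transport lists was weighed against a few non-coding RNAs taking a different share of the counts, which is argued against as the whole cause. Counts were scaled to the coding counts of each library, where those RNAs play no part. The lists still shifted by 1.34 (SE 0.0434) and 0.30 (SE 0.0621, from 3 libraries per group). With total counts the shifts were 1.78 and 0.74. This change of scale moves every gene by the same amount, and genes that rose add to the coding total. In the edgeR fit with coding sequences alone, the list medians were 2.04 and 0.904, against 2.05 and 0.916 with all features. Neither list passed camera with an estimated correlation (adjusted p = 0.108 and 0.101). Lost Hfq and Crc repression of carbon use stays open, since of 68 tested genes for histidine, branched-chain and aromatic catabolism 20 rose (29.4%) and 21 fell, and no genome was at hand to search for its binding motif. Over all 5816 genes tested, 1827 rose and 1864 fell. A different growth rate or density at sampling cannot be told apart from lost repression, since density was recorded only as a range common to both strains. Across coding sequences, which are not independent replicates, log2 fold change had a Spearman rho of -0.0852 with distance from dnaA, which leaves this open.

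The 6 libraries form 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 3691 changed genes and the highest other 0 (edgeR, with up to 47 genes at an unadjusted p under 0.05), and 1 split, the real one, gave as many. For genes changed at least 2-fold the values were 1386 and 0, again with 1 split as large, and for lists past the threshold 15 and 13, also with 1. Every other split puts libraries of both strains in each group, so the strain difference adds to the spread within groups. That lowers the calls, and the 0 genes are no measure of false calls. Every such split also holds more libraries of one strain than of the other in each group. Part of the strain difference thus stays between the groups. These splits gave 4 to 13 lists with camera at the preset correlation, which is no measure of false calls either.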
